A study of Rattus norvegicus with 4 samples.

How the data were processed

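RNA from surface colonocytes of the distal colon of 4 adrenalectomized Wistar rats was hybridized to Affymetrix rat exon arrays, 1 array per rat, after reduction of ribosomal RNA. Per the labels, 2 rats received aldosterone and 2 received vehicle, and the arrays of a group are separate animals. The values analysed were the log2 expression values deposited by the authors, 1 per row and array, where a row is a transcript cluster, the unit of the array that gathers the probes of 1 gene. Per the submitters' processing notes, RMA, Affymetrix Expression Console and Partek were used, with no version, order or role given. RMA subtracts background, makes probe distributions alike across arrays and summarises the probes of a row on the log2 scale. That the values are on a log2 scale was read from their range, 1.36 to 13.7, which is that of RMA values. The genome build and the detection calls of the rows are not given in the sources used here, so no coordinates are printed and rows near background were recognised by level alone. The number of arrays limits the precision.

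Rows were named through the annotation of the array platform, with Entrez gene IDs checked against the RefSeq genes of the GRCr8 rat assembly. Of 19403 rows, 13327 had 1 gene symbol, 620 had several and 5456 had none here, the latter being unnamed rather than without a gene. The named rows covered 13215 genes, of which 102 had more than 1 row, 0 symbols changed through the Entrez ID, and 95 IDs were absent from the RefSeq table. For a gene with several rows the row with the highest mean over the 4 arrays was used. All rows were tested, named or not.

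The comparison of aldosterone with vehicle was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, two-sided), with treatment as the only term, and p-values were adjusted by Benjamini and Hochberg over all rows. The threshold was an adjusted p of 0.05. A count of rows with a fold of 1.5 or more and an unadjusted p under 0.01 was fixed beside it as a description. Intervals are 95% intervals of the moderated fit. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

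Gene lists for corticosteroid response, ion transport, stress and signalling, metabolism and the cell types of the colon were written from general knowledge. Of 30 lists, 29 had measured members. Each was tested with camera at a preset correlation between genes of 0.01, two-sided and adjusted over the lists, which compares a list with all other genes. With this preset its p-value takes genes rather than rats as the units. Camera with a correlation estimated from the data and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were run beside it. Members were also tested adjusted over the list alone. Named in the text are up to 15 genes per direction past the threshold, filled to 12 per direction with the genes of smallest unadjusted p whose groups did not overlap, 13 target genes of aldosterone fixed by name, and up to 4 members of each list with the smallest p. Genes named outside this rule are marked in the text as chosen after their values were seen. The design, lists, naming rule and the first set of alternatives below were written before the data were examined.

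The alternatives fixed in advance were quantile normalization, centring of arrays on their medians, leaving out rows below the 25th percentile or the median of row means (1.89 and 2.35), the replicate number as a block, leaving out each array in turn, a prior variance that follows the mean level (intensity trend), a robust prior, no moderation, an estimated correlation, fry, and the mean over the rows of a gene. With 1 array left out, the group with a single array is assumed to vary like the other. Filters at a mean of 3 and of 4, the intensity trend together with the replicate block, and the intensity trend with arrays left out or regrouped were chosen after seeing the data.

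The fits were tested on simulated data with the real row means and spread, in 20 draws of 200 changed rows with a mean of 4 or more among 19403. The constant prior recovered 3.1% of rows changed by 1 on the log2 scale, 39.4% of those changed by 2 and 89.0% of those changed by 4, with 0.6% false calls among its calls. The intensity trend recovered 25.4%, 98.1% and 100% of them, with 9.4% false calls. Since the simulated spread was drawn from the trend fit, this comparison favours the trend. At an unadjusted p under 0.05, camera found a list of 22 rows shifted by -0.5 in 20 of 20 draws and an unshifted list in 2 of 20. The simulated rows varied independently, so these draws do not show how often camera calls an unshifted list of correlated genes.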

Results

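Gene expression was measured in surface colonocytes of the distal colon, the absorptive epithelial cells that face the gut lumen. The cells came from 4 adrenalectomized Wistar rats aged 12 weeks. All were used 4 days after adrenalectomy and had 0.9% NaCl as drinking water. Removal of the adrenal glands takes away the body's main source of aldosterone, the steroid hormone that raises sodium absorption in the distal colon and the collecting duct of the kidney. The comparison asked which genes differ between 2 rats given aldosterone and 2 rats given vehicle. Aldosterone acted for 2 h, as an injection of 50 µg/100 g body weight and a minipump set to 10 µg/kg per hour. The hormone was also present, at 100 nM, while the cells were shaken off the colon over 40 min. Each rat gave 1 exon array with 19403 rows of log2 values, mostly 1 gene per row. The median of all rows was 2.22 and 2.43 in the vehicle rats and 2.33 and 2.44 in the aldosterone rats. The mean of 65% of rows lay below 3, close to the floor of the arrays. Levels are given as log2 values, mean ± SD over the 2 rats of a group. Differences are aldosterone minus vehicle.

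The gamma subunit gene of the epithelial sodium channel and 3 genes known to respond to corticosteroids, Sgk1, Tsc22d3 and Fkbp5, stood higher in the aldosterone rats. Scnn1g, the gamma subunit gene (row 7036436), stood at 2.04 ± 0.015 in vehicle rats and 7.13 ± 0.68 in aldosterone rats. Sgk1, the kinase that holds this channel at the cell surface (row 7045121), was 3.87-fold higher at 12.53 ± 0.012 against 10.58 ± 0.094. Tsc22d3, which encodes the steroid-induced protein GILZ (row 7383864), was 5.09-fold higher at 10.41 ± 0.036 against 8.07 ± 0.19. Fkbp5, a co-chaperone of steroid receptors (row 7221171), stood at 2.30 ± 0.010 in vehicle rats and at 8.33 and 6.30 in the aldosterone rats. These 4 genes passed the threshold of 0.05 in limma with a prior spread that followed expression level. Their adjusted p was 6.95e-05 for Scnn1g, 0.000558 for Sgk1, 0.00258 for Tsc22d3 and 0.00192 for Fkbp5. With the constant prior fixed as the main test none of them passed, at an adjusted p of 0.402, 0.332, 0.332 and 0.681 in the same order. Over all alternatives the highest adjusted p of each was 1.00. The vehicle means of Scnn1g and Fkbp5 lay below the median of all rows, 2.35, so that their folds are not given.

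**Figure D1:**
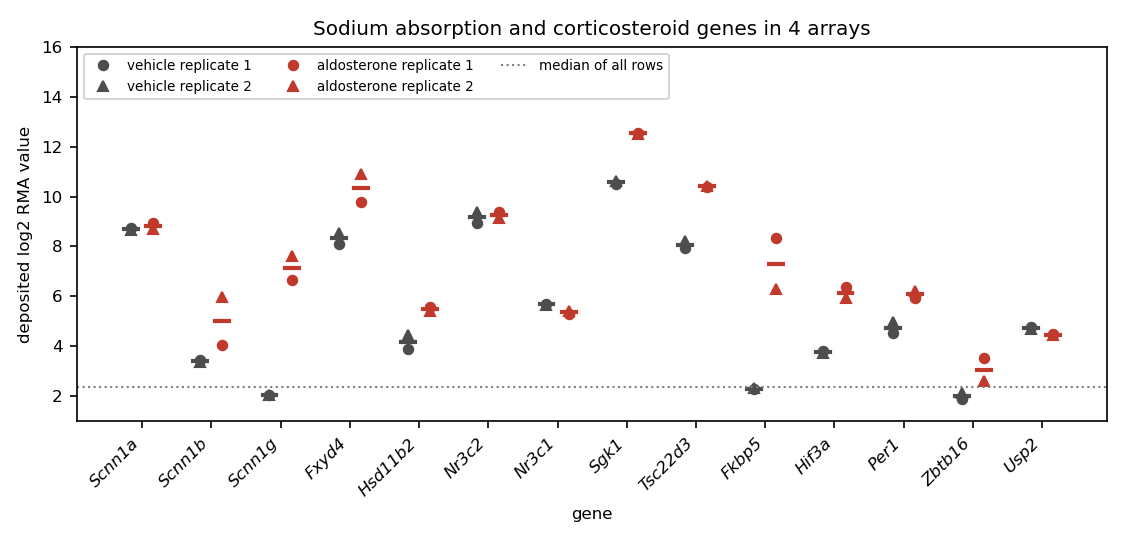
Deposited log2 RMA values (vertical axis) of 14 sodium absorption and corticosteroid genes (horizontal axis) in the 4 arrays, with circles for replicate 1, triangles for replicate 2, short bars for group means, grey for vehicle, red for aldosterone and a dotted line at the median of all rows, 2.35. Scnn1g and Fkbp5 lie below that line in both vehicle rats and above 6 in both aldosterone rats, while Nr3c2 overlaps between the groups.

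The other members of the sodium absorption machinery differed in size and spread. Fxyd4, a regulator of the sodium pump, was 4.09-fold higher in aldosterone rats (10.35 ± 0.79 against 8.32 ± 0.34). Hsd11b2, the enzyme that inactivates glucocorticoids in aldosterone target cells, was 2.51-fold higher (5.50 ± 0.13 against 4.17 ± 0.38). Scnn1b, the beta subunit gene, stood at 3.41 ± 0.049 in vehicle rats and at 4.06 and 5.98 in the aldosterone rats. The 95% interval of its log2 difference ran from -0.25 to 3.47. Scnn1a, the alpha subunit gene, lay at 8.69 ± 0.074 in vehicle rats and 8.81 ± 0.18 in aldosterone rats, with an interval of the difference from -0.26 to 0.49. That difference was -0.011 without aldosterone replicate 1. The mineralocorticoid receptor gene Nr3c2 lay at 9.16 ± 0.30 and 9.26 ± 0.18 (interval -0.44 to 0.63). Its difference was -0.11 without vehicle replicate 1 and -0.0275 without aldosterone replicate 1. The glucocorticoid receptor gene Nr3c1 lay at 5.68 ± 0.023 in vehicle rats and 5.37 ± 0.090 in aldosterone rats. Of the 25 measured genes in the list for electrogenic sodium absorption, 5 rose adjusted over the list alone (Scnn1g, Sgk1, Tsc22d3, Hsd11b2 and Fxyd4). The other 20 did not pass, and with the constant prior 0 passed adjusted over all genes tested. The list shifted upward relative to other genes in camera (median log2 difference 0.11, mean 0.61, adjusted p = 0.00246). This list held 16 members higher and 9 lower, and its mean exceeded its median because a few members rose strongly. Its adjusted p = 0.402 with an estimated correlation, the highest of its alternatives, which began at 2.03e-05. Without vehicle replicate 2 the list median was 0.065 with an adjusted p = 0.321, and without vehicle replicate 1 it was 0.17. With arrays centred on their medians it was 0.0475.

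With the constant prior, 0 of the 27 measured genes of the corticosteroid-induced list passed adjusted over all genes tested. Adjusted over the list alone, 21 did not pass and 6 rose. Besides Sgk1, Tsc22d3 and Fkbp5 they were Hif3a, Per1 and Cebpb. Hif3a, a member of the hypoxia-inducible factor family, stood at 6.15 ± 0.31 against 3.78 ± 0.066 (5.19-fold). Per1, a clock gene with corticosteroid response elements, stood at 6.09 ± 0.20 against 4.74 ± 0.30 (2.54-fold). Cebpb, a transcription factor gene named after its values were seen, stood at 6.32 ± 0.12 against 5.32 ± 0.39. Zbtb16, which encodes a zinc finger protein, lay at 3.51 and 2.59 in the aldosterone rats against 2.02 ± 0.17, a vehicle mean below the median of all rows. Usp2, which encodes a deubiquitinase, lay at 4.47 ± 0.016 against 4.74 ± 0.063. Rasd1, a Ras-related gene known to be induced by dexamethasone, lay at 6.95 and 8.35 in the aldosterone rats against 9.05 ± 0.20 in vehicle rats. The list shifted upward in camera (median 0.19, mean 0.50, adjusted p = 0.00602), with 17 members higher and 10 lower. Its adjusted p = 0.514 with an estimated correlation, and the alternatives ran from 8.06e-07 to 0.514. The call ended without vehicle replicate 2 (median 0.14, adjusted p = 0.196) and without aldosterone replicate 1 (median 0.081, adjusted p = 0.0918). The median was 0.074 without vehicle replicate 1, 0.31 without aldosterone replicate 2 and 0.31 with rows below a mean of 3 left out. Sgk1, Tsc22d3 and Usp2 are among the genes that belong to both this list and the sodium absorption list. Rasd1 and Dusp1 are among those shared with the list of MAPK feedback genes below. The results of these lists are therefore not independent.

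The genes named next had some of the smallest unadjusted p-values among those whose groups did not overlap. None of them passed the threshold in limma with the constant prior (adjusted p from 0.332 to 0.487). With the intensity trend Cyp27a1, Hhex, Noct, Mcoln2 and Plk2 passed, and the others did not. Cyp27a1, the mitochondrial sterol 27-hydroxylase, was 4.63-fold higher in aldosterone rats (8.64 ± 0.16 against 6.43 ± 0.12). Nr1h4, which encodes the bile acid receptor FXR, was 2.48-fold higher (6.48 ± 0.15 against 5.16 ± 0.055). Slc38a1, a glutamine transporter gene, stood at 9.43 ± 0.0055 against 8.17 ± 0.13 (2.39-fold). Mcoln2, which encodes a lysosomal cation channel, was 5.02-fold higher, and Noct, which encodes the clock-controlled protein nocturnin, 4.54-fold. The homeobox gene Hhex stood at 4.18 ± 0.25 against 2.27 ± 0.049, a vehicle mean below the median of all rows. The DNA repair nuclease gene Dclre1b was 2.74-fold higher and Apbb3, which encodes an adaptor of the amyloid precursor protein, 2.26-fold. In the lower direction, Hbegf, a ligand of the EGF receptor, lay at 8.19 ± 0.041 against 9.37 ± 0.0044 (2.25-fold lower). Fgf9, a fibroblast growth factor gene, lay at 4.30 ± 0.10 against 5.66 ± 0.073 (2.56-fold lower). Mst1r, which encodes the receptor tyrosine kinase RON, lay at 6.62 ± 0.043 against 7.88 ± 0.041 (2.38-fold lower). Plk2, a polo-like kinase gene, was 3.42-fold lower (7.17 ± 0.15 against 8.95 ± 0.31). The galactosyltransferase gene B4galt6 was 3.05-fold lower, the kinase gene Ripk4 2.46-fold, the stress-induced transcription factor gene Atf3 2.46-fold and the somatostatin receptor gene Sstr2 2.24-fold. The mitochondrial phosphatase gene Pptc7, the alpha-actinin gene Actn2 and Mllt11 were lower by 1.95-fold to 2.05-fold. The chemokine gene Cxcl6 lay at 2.31 and 2.41 in the aldosterone rats, close to the median of all rows, against 3.43 ± 0.056, so that its fold is not given.

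None of the 19403 rows passed an adjusted p of 0.05 in limma with a constant prior (smallest adjusted p = 0.332). An unadjusted p under 0.05 was found in 879 rows (4.53%), no more than chance gives at that threshold. Of these, 425 were higher and 454 lower in aldosterone rats, a split that became 281 and 508 with each array centred on its median. A fold of 1.5 or more together with an unadjusted p under 0.01 was found in 196 rows, 102 higher and 94 lower (79 and 107 after centring). Splitting the arrays by replicate number in place of treatment gave 206 such rows. Both values of one group lay beyond both values of the other in 3235 rows higher and 2161 rows lower with aldosterone, together 27.8% of rows, where chance gives 33.3%. A robust prior and a fit without moderation called 0 rows. A prior that followed expression level called 21 rows, of which 18 rose, 3 fell and 20 carried a gene name. Scnn1g, Sgk1, Tsc22d3, Fkbp5, Hif3a, Cyp27a1, Hhex, Noct and Mcoln2 were among those that rose. The others were Slc12a2, which encodes the sodium-potassium-chloride cotransporter NKCC1, Arg2, which encodes mitochondrial arginase (9.04-fold), Padi2, a peptidylarginine deiminase gene (6.80-fold), Cdc37l1, Klhl42, Tle4, Hsd3b2, Fads3 and an unnamed row. Those that fell were Plk2, the immunoproteasome gene Psmb8 (6.60 ± 0.068 to 4.43 ± 0.57) and Duoxa2, a maturation factor of a hydrogen peroxide-producing oxidase (8.03 ± 0.43 to 4.94 ± 1.28). Arg2, Padi2, Cdc37l1, Klhl42, Tle4, Hsd3b2, Fads3 and Duoxa2 were named after their values were seen. The same fit called 7 rows without vehicle replicate 1, of which Scnn1g and Sgk1 were among the 21, and 8 without vehicle replicate 2, of which Scnn1g, Sgk1 and Tsc22d3 were. With either aldosterone array left out it called more rows, but the spread then came from the vehicle rats alone. Over rows with a mean of 4 or more, the difference between the vehicle arrays had an SD of 0.481. That between the aldosterone arrays had an SD of 0.577. These fits therefore do not show that the 21 calls are firm.

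**Figure D2:**
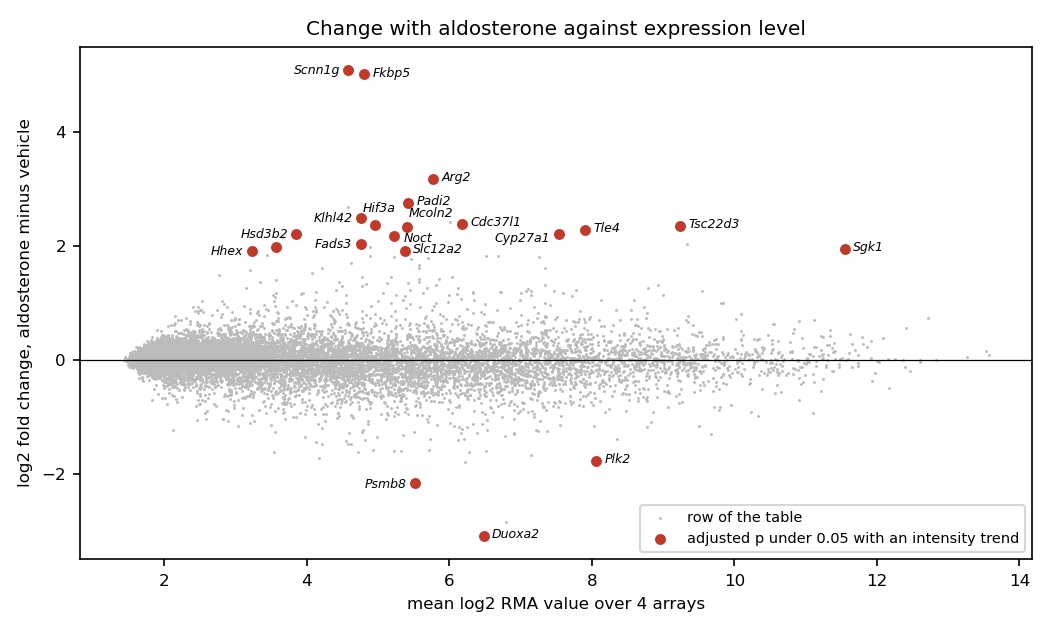
Log2 fold change of aldosterone over vehicle (vertical axis) against the mean log2 RMA value over the 4 arrays (horizontal axis) for all 19403 rows in grey, with the 21 rows that passed an adjusted p of 0.05 in limma with an intensity trend in red. The 18 red points above 0 include Scnn1g and Fkbp5 near 5, and the 3 below 0 are Plk2, Psmb8 and Duoxa2.

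Genes of other colonic ion transport shifted upward as a list in camera (29 measured, 21 of them higher, median 0.27, adjusted p = 0.00246). Its adjusted p = 0.402 with an estimated correlation, and the alternatives ran from 2.96e-05 to 0.413. Members such as Slc26a3 also belong to the surface colonocyte markers below, so that the results of these lists are not independent. Slc12a2 rose adjusted over the list alone, at 6.33 ± 0.0036 against 4.42 ± 0.35 (3.77-fold), and 28 members did not pass. Best2, an anion channel gene, lay at 3.52 ± 0.62 against 2.02 ± 0.0035, a vehicle mean below the median of all rows. Kcne3, a potassium channel subunit gene, lay at 4.32 ± 0.050 against 3.28 ± 0.50. Trpm6, a magnesium channel gene, lay at 7.72 and 7.29 against 6.79 and 6.89 (1.58-fold). The 14 measured tight junction genes did not shift (median -0.11, adjusted p = 0.333). The claudin gene Cldn4 lay at 10.37 ± 0.28 against 10.82 ± 0.21, and Cldn8, a claudin that limits back-leak of sodium in the colon, at 5.93 ± 0.38 against 5.52 ± 0.016.

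Of 22 measured genes of the immediate early response, 6 fell adjusted over the list alone, 16 did not pass, and 0 passed adjusted over all genes tested. The difference was negative in 20 of the 22. The list shifted downward in camera (median -0.51, adjusted p = 3.21e-12) and moved one way in fry (adjusted p = 0.00152). Its adjusted p = 0.402 with an estimated correlation, and the alternatives ran from 1.43e-12 to 0.402. That estimated correlation was -0.0348, below the preset 0.01, so that a higher correlation between the genes does not account for the loss. With the preset, camera takes genes as its units. A small p-value from it, for this or any other list, does not measure the spread between the 2 rats of a group. Atf3 stood at 9.02 ± 0.18 against 10.32 ± 0.0057, and Nr4a2, an orphan nuclear receptor gene, at 5.71 ± 0.34 against 7.32 ± 0.39. Ier3, an early response gene tied to survival, stood at 6.49 and 7.01 against 8.16 and 7.83, and Klf2, a Krüppel-like factor gene, at 5.25 ± 0.091 against 5.83 ± 0.10. The other members that fell were Fosb and Nr4a1, both named after their values were seen. The 13 measured genes of MAPK feedback, which are themselves induced by growth factor signalling, also shifted downward (median -0.35, adjusted p = 9.78e-05, 11 of 13 lower). The adjusted p of that list = 0.402 with an estimated correlation, within alternatives from 3.59e-06 to 0.402. No member of that list passed adjusted over the list alone. Dusp5, an ERK phosphatase gene, lay at 8.28 ± 0.41 against 9.37 ± 0.13, and Dusp4, another MAP kinase phosphatase gene, at 2.61 ± 0.12 against 3.58 ± 0.63.

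Heat shock and interferon response genes shifted in opposite directions in camera, and both calls ended at an adjusted p = 0.402 with an estimated correlation. Among 9 measured heat shock genes, 2 rose adjusted over the list alone, the co-chaperone genes Dnajb1 (9.12 ± 0.30 against 8.07 ± 0.23) and Bag3 (7.98 ± 0.13 against 7.28 ± 0.15), and 7 did not pass. The list median was 0.21 (adjusted p = 0.0146), with an adjusted p = 0.402 with an estimated correlation and alternatives from 0.00114 to 0.413. That call ended without vehicle replicate 2 (median 0.23, adjusted p = 0.292) and without aldosterone replicate 1 (median 0.16, adjusted p = 0.138). The median was 0.44 without vehicle replicate 1, 0.40 without aldosterone replicate 2 and 0.40 with rows below a mean of 3 left out. Of 17 measured interferon response genes, Psmb8 fell adjusted over the list alone and 16 did not pass. Irf1, an interferon-induced transcription factor gene, lay at 6.06 and 5.93 against 7.41 and 6.70, and Oasl, an oligoadenylate synthetase-like gene, at 6.61 ± 0.26 against 7.15 ± 0.097. The interferon list had a median of -0.10 (adjusted p = 0.00891), with an adjusted p = 0.402 with an estimated correlation and alternatives from 0.00540 to 0.413. Its median was -0.0415 with an adjusted p = 0.162 without vehicle replicate 1, and -0.16 without aldosterone replicate 2. The size of this shift depended on rows of low level, with a median of -0.21 with rows below the 25th percentile left out, -0.36 below the median and -0.38 below a mean of 3. With arrays centred on their medians it was -0.16. Inflammatory genes (21 measured) had a median of -0.011, a mean of 0.039 and a downward camera statistic (adjusted p = 0.626). MHC class II genes (10 measured) had a median of -0.12 (adjusted p = 0.626), which became -0.24 with an adjusted p = 0.00164 without aldosterone replicate 2, within alternatives that reached 0.981. Nfkb2, a subunit gene of NF-kappa B, lay at 5.33 ± 0.058 against 5.79 ± 0.24, and the class II gene RT1-DMa at 6.60 ± 1.16 against 7.83 ± 0.91.

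Lists of the clock and of metabolism did not shift. Clock genes (14 measured) had a median of 0.021, a mean of 0.059 and a downward camera statistic (adjusted p = 0.905). Per1 rose adjusted over that list alone, while Cry2 and Nr1d1, repressors of the clock, lay at 6.99 ± 0.21 against 7.54 ± 0.14 and 8.47 ± 0.10 against 8.96 ± 0.21. Fatty acid oxidation and ketogenesis genes (16 measured) had a median of 0.018, a mean of -0.038 and a downward statistic (adjusted p = 0.905). Cpt1a, the gate of mitochondrial fatty acid uptake, lay at 8.18 ± 0.10 against 8.78 ± 0.060. Cholesterol synthesis genes (12 measured) had a median of 0.11 and a mean of 0.0445 with a downward statistic (adjusted p = 0.905). Their median turned to -0.89 without aldosterone replicate 1 (adjusted p = 5.09e-09) and reached 0.74 without aldosterone replicate 2 (adjusted p = 7.29e-10), within alternatives that reached 0.999. The unfolded protein and amino acid response (15 measured) had a median of -0.067 (adjusted p = 0.626). It held Herpud1, a gene of endoplasmic reticulum protein degradation, at 9.34 ± 0.086 against 8.79 ± 0.14 and Ddit3, which encodes CHOP, at 5.58 ± 0.20 against 6.51 ± 0.39. Hypoxia and glycolysis genes (14 measured) had a median of -0.21 (adjusted p = 0.131), which became -0.30 with an adjusted p = 0.000733 without aldosterone replicate 1, within alternatives that reached 0.981. Ribosomal protein genes (23 measured) had a median of 0.0077 (adjusted p = 0.905). Genes of the mitochondrial respiratory chain (63 measured) had a median of 0.070 (adjusted p = 0.614), which became 0.18 with an adjusted p = 0.000143 without aldosterone replicate 1, within alternatives that reached 0.981.

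Markers of surface colonocytes shifted slightly upward in the aldosterone rats, with 13 of 15 measured members above 0, a median of 0.17 and an adjusted p = 0.00891 in camera. The adjusted p = 0.402 with an estimated correlation, and the alternatives ran from 0.00619 to 0.865. None of the markers passed adjusted over the list alone. The chloride-bicarbonate exchanger gene Slc26a3, which belongs to the ion transport list too, lay at 12.68 ± 0.096 against 12.13 ± 0.24. Fabp2, a fatty acid binding protein gene, lay at 4.25 and 4.74 against 3.65 and 3.77. The call ended without vehicle replicate 2 (median 0.22, adjusted p = 0.0704). The median was 0.085 without vehicle replicate 1 and 0.11 with arrays centred on their medians. Crypt and proliferation markers (16 measured, median level 2.27) had a median difference of 0.12 (adjusted p = 0.0209), with an adjusted p = 0.969 with an estimated correlation and alternatives from 0.00117 to 0.969. Tuft cell markers (7 measured, median level 3.01) had a median difference of 0.23 (adjusted p = 0.0209), with an adjusted p = 0.738 with an estimated correlation and alternatives from 0.0172 to 0.738. No member of either list passed adjusted over the list alone. Axin2, a Wnt target gene, lay at 3.36 ± 0.22 against 2.72 ± 0.0050, and the tuft cell kinase gene Dclk1 at 3.54 ± 0.079 against 3.31 ± 0.020. The crypt call ended without vehicle replicate 1 (median 0.038, adjusted p = 0.422) and without aldosterone replicate 1 (0.0535, adjusted p = 0.657), and its median was 0.21 without vehicle replicate 2. It also ended with quantile normalization (0.075, adjusted p = 0.0534), and the median was 0.059 with arrays centred on their medians. The tuft call ended without vehicle replicate 1 (0.058, adjusted p = 0.422), aldosterone replicate 1 (0.19, adjusted p = 0.105) and aldosterone replicate 2 (0.18, adjusted p = 0.116).

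Markers of the remaining cell types did not pass the threshold in camera. Goblet cell markers (10 measured) had a median of 0.16 (adjusted p = 0.626). Zg16, which encodes a lectin of the mucus granule, stood at 6.39 and 8.06 in the aldosterone rats against 4.80 ± 0.49. The goblet median became 0.49 with an adjusted p = 0.00106 without aldosterone replicate 1, within alternatives that reached 0.981. Enteroendocrine markers (14 measured) had a median of 0.023, a mean of -0.012 and a downward statistic (adjusted p = 0.894). Lymphocyte markers (17 measured) had a median of 0.011, a mean of 0.015 and a downward statistic (adjusted p = 0.905). Smooth muscle markers (9 measured) had a median of 0.0022, a mean of 0.0054 and a downward statistic (adjusted p = 0.905). Myeloid (17 measured), fibroblast (13 measured) and endothelial markers (7 measured) had medians of 0.028, 0.085 and 0.057 (adjusted p = 0.905, 0.626 and 0.626). The macrophage gene Mrc1 lay at 3.77 ± 0.34 against 4.64 ± 0.12. Enteric neuron and glia markers (9 measured) had a median of 0.16 with 8 of 9 higher (adjusted p = 0.131). Red blood cell genes (3 measured) had a median of 0.22 (adjusted p = 0.626). The red blood cell median became 0.44 with an adjusted p = 0.00351 without aldosterone replicate 1, within alternatives that reached 0.981.

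**Figure D3:**
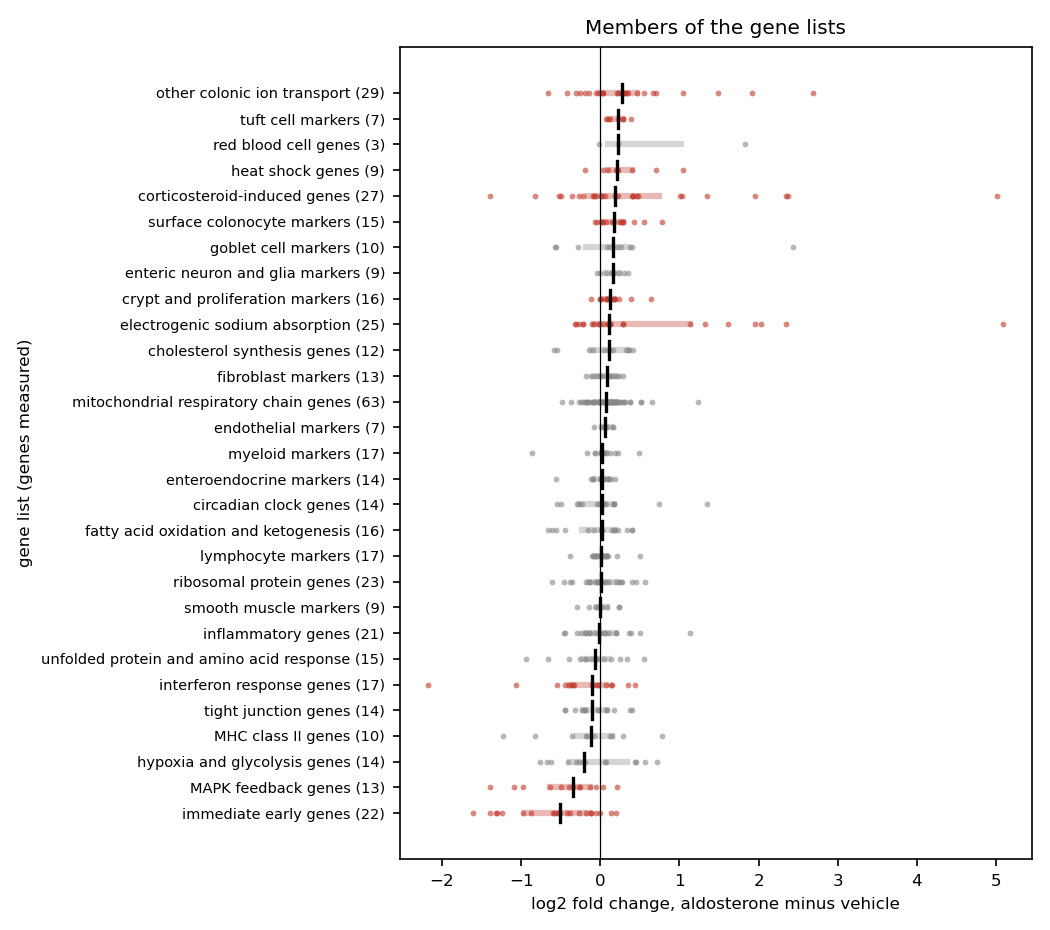
Log2 fold change of aldosterone over vehicle (horizontal axis) for the measured members of 29 gene lists (vertical axis), with a point for each gene, a pale bar between the quartiles, a black tick for the median and red for the 10 lists past an adjusted p of 0.05 in camera with the preset correlation. The immediate early genes have the lowest median, -0.51, and other colonic ion transport the highest, 0.27.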

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

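The filters at a mean of 3 and 4, the intensity trend with the replicate block and the trend fits with arrays left out or regrouped were chosen only after the result was seen. The count of 0 rows past the threshold became 1 with rows below the median left out and 1 below a mean of 3 (Scnn1g both times), 12 below a mean of 4, all higher and all among the 21 called with the intensity trend. Fewer rows were tested in these filters. The prior degrees of freedom, the weight given to the spread pooled over rows, also rose from 2.1 to 4.99, 4.98 and 5.36 in the same order. The share of each in the calls was not tested. It remained 0 under the other planned settings of the constant prior. The replicate numbers do not pair the rats in the labels, and same-number deviations correlated at 0.148 over all rows and 0.0934 over rows with a mean of 4 or more. With the replicate block the constant prior called 0 rows, had 1282 rows at an unadjusted p under 0.05 in place of 879, and 271 by fold and p. With the intensity trend and the replicate block it called 6, all among the 21. With the intensity trend, the split of the 4 arrays by replicate number called 0 rows and the remaining split 1, against 21 for the treatment, and 3 splits are too few for a share under 0.05. The 196 rows by fold and unadjusted p became 36 without moderation, 124 with a filter at 3 and 103 with a filter at 4, and ran from 192 to 274 with 1 array left out.

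Of 505 alternatives for 34 named genes, 477 stayed on the same side of the threshold in the same direction, 25 passed it, and 3 reversed. Those were Nr3c2, from -0.11 without vehicle replicate 1 to 0.31, with -0.0275 without aldosterone replicate 1, and Scnn1a, from -0.011 without aldosterone replicate 1 to 0.25. For the 10 lists that shifted, 91 of 130 alternatives kept the call, and 39 ended it with the direction kept. With an estimated correlation all 10 calls ended, and with fry only the immediate early call held. Neither method can change the list medians, 0.19 (corticosteroid-induced), 0.11 (sodium absorption), 0.27 (other ion transport), -0.51 (immediate early) and -0.35 (MAPK feedback). The others were 0.21 (heat shock), -0.10 (interferon), 0.17 (surface colonocyte), 0.12 (crypt) and 0.23 (tuft). The calls for crypt and tuft markers also ended with quantile normalization (0.075 and 0.21), rows below the median left out (0.13 and 0.26) and rows below a mean of 3 left out (0.13 and 0.26), tuft with rows below the 25th percentile left out (0.23) and crypt with the replicate block (0.12), and the block ended no other call. Between rats of the same number, in the order of the lists above, medians for replicate 1 were 0.18, 0.015, 0.22, -0.52, -0.094, 0.17, -0.21, 0.069, 0.23 and 0.30, and for replicate 2 were 0.048, 0.20, 0.13, -0.50, -0.53, 0.29, -0.10, 0.11, -0.021 and 0.14. The block also brought enteric neuron and glia markers past the threshold (adjusted p = 0.0429, alternatives up to 0.969). With 1 array left out, medians ran from 0.074 to 0.31 for corticosteroid-induced genes, 0.065 to 0.17 for sodium absorption, 0.16 to 0.44 for heat shock, -0.16 to -0.0415 for interferon, 0.085 to 0.22 for surface colonocytes, 0.038 to 0.21 for crypt and 0.058 to 0.24 for tuft markers. Among 19 lists that did not shift, 234 of 242 alternatives stayed without a call, 7 passed the threshold, and cholesterol synthesis reversed, from -0.89 without aldosterone replicate 1 to 0.74 without aldosterone replicate 2. The cause of these moves was not tested. The estimated correlation was below the preset 0.01 for sodium absorption (0.0025), immediate early (-0.0348), MAPK feedback (-0.0587), heat shock (-0.0802) and surface colonocyte genes (-0.0599). It was above 0.01 for corticosteroid-induced (0.0549), other ion transport (0.0316), interferon (0.011), crypt (0.48) and tuft genes (0.27). Higher correlation therefore does not account for the lost calls of the former lists. Interferon lost its call close to the preset. Only with an estimated correlation does camera use the 2 residual degrees of freedom. The lost calls are thus no sign of correlated genes.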

Other observations

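Some gene groups differed more between the rats of one group than between the groups. Cholesterol synthesis genes averaged 6.56 and 7.02 in the vehicle rats and 7.64 and 6.03 in the aldosterone rats, so that the highest and the lowest mean both belonged to aldosterone rats. Msmo1, a sterol methyl oxidase gene, stood at 5.92 and 7.70 in vehicle rats and 8.53 and 5.91 in aldosterone rats, and Idi1, an isopentenyl diphosphate isomerase gene, at 4.08 and 5.64 against 6.76 and 3.70. Both genes were chosen after their values were seen. Goblet cell markers averaged 6.82 and 6.99 in vehicle rats and 6.73 and 7.57 in aldosterone rats, and MHC class II genes 4.25 and 4.77 against 3.93 and 4.79. The globin gene Hbb-b1 stood at 5.91 and 5.28 in vehicle rats, 5.06 in aldosterone replicate 1 and 9.79 in aldosterone replicate 2.

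Of the tests below, that of handling stress was chosen only after the result was seen. For the lower immediate early genes, the list with the smallest p-value, the tables argue against unequal scaling of the arrays, since after quantile normalization the list median lay -0.53 from the median of all genes, which was 0.004. Fewer cells other than epithelium stay open, because only Cd14 (11.01 in vehicle rats), Fbln1 (5.65, a gene chosen after its values were seen) and Mrc1 (4.64), 3 of 63 measured markers, had a mean of 4 or more, with a median difference of -0.044 and an interval of -0.54 to 0.82 for its distance from the list. Less handling stress in the aldosterone rats cannot be told apart from an effect of the hormone, since the 9 heat shock genes, 8 of them higher, had a median of 0.21, short of the bound of 0.25 set against it. That median lay on both sides of the bound in the alternatives, from 0.16 to 0.44 with 1 array left out and at 0.40 with rows below a mean of 3 left out. The heat shock genes Hspa1a, Hspa1b, Hsp90aa1, Hspa8 and Hspd1 had no row named for them alone. Of the 9 measured, 4 had a mean of 4 or more, which limits this test further. An effect of aldosterone on the immediate early genes stays open as a hypothesis, and both groups were shaken for 40 min before RNA was taken.

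More rows differed by replicate number than by treatment with the constant prior. An unadjusted p under 0.05 was found in 10.6% of rows against 4.53%, with 0 past the threshold in either. The intensity trend kept this order, with 1766 rows by replicate number and 907 by treatment. However, it called 0 rows past the threshold by replicate number and 21 by treatment. By fold and unadjusted p it gave 156 rows by replicate number and 217 by treatment, where the constant prior gave 206 and 196. Unequal value distributions may account for part of the higher share by replicate number but not all. After quantile normalization 7.94% of rows still differed by replicate number, against 5.75% by treatment. Rows near background may contribute, since among rows with a mean of 4 or more the share was 6.67%, against 6.13% by treatment, which lies between the bounds set in advance. A shared day or batch of the same-numbered rats stays untested, as the labels name none.

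The aldosterone rats also differed in the level of the higher genes. Of the 102 higher rows with a fold of 1.5 or more and an unadjusted p under 0.01, 72 (70.6%) had their higher value in aldosterone replicate 1, between the bounds set in advance, so that a generally stronger response of that rat cannot be told apart from differences gene by gene. Fkbp5 was higher in aldosterone replicate 1, whereas Scnn1g, Scnn1b and Fxyd4 were higher in aldosterone replicate 2.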
